A study of Homo sapiens with 4 samples.

How the data were processed

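The study expressed ADAR2 or its mutants stably in Kasumi-1 cells by retroviral transduction from a packaging cell line, with selection by puromycin or FACS, per the labels. RNA was taken with Trizol and libraries were made with the TruSeq stranded total RNA kit, per the labels. RNAs without a poly(A) tail were scarce for such a kit, with 8 of 61 listed histone genes at 1 CPM and RN7SK at 2.57 to 21.6 CPM, and whether poly(A) selection was used or the ADAR2 library was made with the others is not given in the sources used here. The groups are EV, ADAR2, AR2-dsRBD and AR2-Cat, with 1 library each. The labels do not spell out these short names, which are kept as given.

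Reads were aligned with STAR to GRCh38 (hg38) and counted with featureCounts, per the submitters' processing notes. Versions of these tools are not given in the sources used here, and neither is the strand setting of the counting. The deposited tables hold read counts per gene, as made by the authors, and the authors' RPKM values of the same genes. Dividing counts by the deposited RPKM gave a gene length within 0.05 of a whole number for 32714 of 32714 genes that could be tested. Even numbers made up 74.2%, 82.8%, 74.1% and 78.8% of the counts from 1 to 20 in EV, ADAR2, AR2-dsRBD and AR2-Cat, as when both mates of a pair are counted. Counts were therefore halved for the printed counting intervals. The calls used the counts as deposited, and calls from halved counts were tried as an alternative. Of 60608 lines, 3 were broken and left out. Symbols were matched to RefSeq for 39402 genes, and 20417 lines carried Ensembl identifiers.

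Computed here were TMM factors and CPM, which are counts scaled to the effective library size, with edgeR 4.0.16 in R 4.3.3, with a prior count of 2 for log2 ratios. The TMM factors were 1.059, 0.902, 1.045 and 1.002. Size factors of DESeq2 1.42.0 served as an alternative, and figures were drawn in Python 3.11.15 with matplotlib 3.10.9. Genes with at least 1 CPM in at least 1 library were kept, 15816 in number, 11450 of them protein-coding. A call needed a log2 ratio of 1 in either direction, 50 reads over the pair, and a 95% interval from the binomial distribution that excluded no change. These intervals, and the floor of 3 single reads used where a library had no reads, cover counting error and nothing else. No P values were computed. Depth, as counts summed over genes, differed from 131570614 to 193229903, and thinning to the shallowest library was an alternative.

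Genes were named by rule, as the 10 widest protein-coding ratios in each direction against EV, 5 in the other pairs and in the comparison of each library with the other 3, from genes other than histones with at least 100 reads. Up to 4 members of each gene list with at least 50 reads over the pair were named too. Names outside this rule, were chosen after their values were seen. ADARB1, ADAR, ADARB2, COPA, COG3, RUNX1 and RUNX1T1 were always given. The 35 gene lists hold 852 entries, 818 of them in the tables. A list of at least 5 measured members was called apart when its median lay below the 2.5 or above the 97.5 percentile of 10000 random lists matched on mean expression, as a description of these libraries. Of 30 lists tested per pair, 10 were called in ADAR2, 17 in AR2-dsRBD and 16 in AR2-Cat against EV. For lists of genes drawn at random, 1.5 would be called. That figure leaves out genes that move together and differences between single cultures. It is not the count without an effect of the constructs. Between AR2-dsRBD and AR2-Cat, 4 lists were called higher and 4 lower, and in ADAR2 against each mutant 8 higher and 4 lower.

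The scaling, filters, rule of size, lists and all other alternatives were chosen before the data were examined. Removal of the length trend, intervals from read pairs, TMM factors without the ADAR2 library, and random lists matched on length were chosen after seeing the data, as were the split of the stress response list and the gene families. In a test with planted differences, 100 of 100 genes with a 4-fold difference were called, 0 of 100 with a 1.5-fold difference and 0 of 15157 unchanged genes, and 6 of 174 unchanged lists. The simulated counts held counting error alone, with no spread between cultures or library preparations. The test therefore checks the rule and gives no rate of false calls for these libraries. RNA editing levels were not analysed here, nor were GC content and splice forms.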

Results

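The series measured messenger RNA levels by RNA sequencing in cells labelled Kasumi-1, a human acute myeloid leukaemia line, that carried 1 of 4 retroviral constructs. The constructs were EV, ADAR2, AR2-dsRBD and AR2-Cat. ADAR2 is the adenosine-to-inosine RNA editing enzyme encoded by ADARB1, and the last 2 constructs are the ADAR2 mutants of the labels' protocol. EV served as the control. Each group held 1 library, so no difference given here has a replicate check. Counts summed over genes were 162668783 (EV), 193229903 (ADAR2), 131570614 (AR2-dsRBD) and 143977109 (AR2-Cat). Overlapping features can each count the same read, as RN7SK and 7SK had identical counts in all 4 libraries. These sums can therefore exceed the reads that were counted. The totals behind the deposited RPKM values were lower in each library. Numbers of genes called can likewise include features that share reads. Of 60605 genes, 15816 reached 1 CPM (counts scaled to library size) in at least 1 library and were compared. A gene was called higher or lower when the CPM of a pair of libraries differed by at least 1 on the log2 scale, with at least 50 reads between them and a 95% counting interval that excluded no change. Such a call compares the 2 libraries and not the constructs.

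ADARB1 was measured first, as the gene that the constructs carry. It had 4010 reads in EV, 108186 in ADAR2, 135530 in AR2-dsRBD and 115780 in AR2-Cat. Its level was 26.6-fold higher in ADAR2 than in EV (log2 ratio 4.74, 95% counting interval 4.67 to 4.80), 42.3-fold higher in AR2-dsRBD (log2 ratio 5.40, 5.34 to 5.47) and 34.4-fold higher in AR2-Cat (log2 ratio 5.11, 5.04 to 5.17). The other deaminase genes did not follow it. ADAR, which encodes ADAR1, had log2 ratios against EV of -0.27 in ADAR2, 0.17 in AR2-dsRBD and 0.09 in AR2-Cat, and ADARB2 had no reads. The 14 measured genes of the ADAR family and its cofactors had medians of 0.10, 0.26 and 0.26, of which the AR2-dsRBD median stood apart from 10000 random lists matched on mean expression (percentile 99.01) and the AR2-Cat median did so with length-matched lists alone (98.23), and the sign in ADAR2 changed with scaling. The ADAR family includes ADARB1, the gene of the constructs, and 1 member of this list passed the rule upward in each construct. FMR1 (-1.52), an RNA-binding protein gene, was lower in ADAR2. Transcripts of COPA and COG3, known substrates of ADAR2, stayed within the limit of 1. COPA had log2 ratios of -0.59, -0.28 and -0.32, and COG3 of -0.51, 0.17 and 0.07, in the same order.

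The transcript content was that of myeloid cells, with exceptions that include the fusion gene that defines the named line. Kasumi-1 is known to carry the RUNX1-RUNX1T1 fusion, but RUNX1T1 had 0 reads in all 4 libraries, where a limit of 3 single reads is 0.0174 CPM in EV, 0.0172 in ADAR2, 0.0218 in AR2-dsRBD and 0.0208 in AR2-Cat, and a limit of 3 read pairs is higher. RUNX1 itself was abundant, at 55849 reads in EV, 33251 in ADAR2, 38949 in AR2-dsRBD and 38293 in AR2-Cat. CD34, a stem cell surface marker for which the line is usually positive, had 6, 28, 12 and 13 reads. PROM1 and TRH had 0 reads in all 4 libraries, BAALC had 2, 10, 1 and 0, and ERG 10, 8, 8 and 12. KIT (7.88, 3.11, 4.41 and 5.74 CPM) and POU4F1 (2.16, 0.907, 1.76 and 1.65 CPM) were measurable. Of 27 stem and progenitor genes in the tables, 18 were under 1 CPM in every library. The rest included FLT3, a cytokine receptor, with 82874, 56271, 49391 and 56435 reads, and the homeobox genes HOXA9 (78.2, 61.5, 71.5 and 74.6 CPM) and MEIS1 (65.3, 45.2, 59.0 and 58.0 CPM). Azurophil granule genes covered a wide range, with AZU1 at 411, 636, 429 and 443 CPM and ELANE, neutrophil elastase, at 233, 439, 312 and 310 CPM, and MPO, myeloperoxidase, at 19.2, 21.2, 19.2 and 17.9 CPM. CD34, PROM1, TRH, BAALC, ERG, HOXA9, AZU1, MPO and the CPM of ELANE, KIT and POU4F1 were singled out after their values were seen.

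Against EV, the ADAR2 library had higher levels of nuclear genes for respiration and of ribosomal protein genes, and lower levels of mitochondrially encoded mRNAs and of many long genes. All 32 measured nuclear genes of oxidative phosphorylation lay above 0, 15 of them past the rule of size, with a list median of 0.99 on the log2 scale. NDUFB7 (1.39), NDUFS5 (1.33), ATP5ME (1.31) and NDUFS6 (1.31), subunits of complex I and of ATP synthase, led that list. All 53 cytosolic ribosomal protein genes lay above 0 as well, with a median of 0.77 and 3 past the rule, RPL35 (1.06), RPS15 (1.01) and RPS28 (1.00). The 13 mitochondrially encoded mRNAs all lay below 0, with a median of -1.36 and 10 past the rule, among them MT-ND4L (-3.11), MT-ND5 (-2.43) and MT-ATP8 (-2.15). Mitochondrial genes made up 1.00% of the counts in ADAR2, 2.66% in EV, 1.98% in AR2-dsRBD and 1.92% in AR2-Cat.

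In all, 579 genes were higher and 1493 lower in ADAR2 than in EV. After ADARB1, the widest higher ratios belonged to S100A8 (7.61-fold, 184 against 22 reads), a calcium-binding protein of neutrophils, AIG1 (5.96-fold), HMOX1 (5.03-fold), which encodes haem oxygenase 1, FXYD1 (4.36-fold), PNCK (4.27-fold), PRR33 (4.02-fold), PLAAT4 (3.91-fold), TNNI3 (3.66-fold) and ALDOC (3.53-fold), an aldolase of glycolysis. ALDOC had 35277 against 9882 reads and HMOX1 1384 against 270. The widest lower ratios were those of PAPPA2 (24.9-fold, 6 against 200 reads), CNTN4 (19.7-fold), CCDC144A (13.6-fold), SYCP2 (8.87-fold), MARCHF1 (8.59-fold), PGAP1 (8.24-fold), KLHDC7B (7.78-fold), ZBTB4 (7.37-fold), LPAR4 (6.82-fold, 326 against 2210 reads) and PEG3 (6.52-fold).

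Among smaller groups, glycolysis genes had 4 members higher and 2 lower, with PKM (1.20) and ENO1 (1.15) among the first and PDK1 (-1.03), a kinase that restrains pyruvate oxidation, among the second. Their list median of 0.37 was not apart from random lists matched on expression (percentile 95.10) but was with lists also matched on length (99.63). Cholesterol synthesis genes had 5 members higher, including EBP (1.33), TM7SF2 (1.12), MVD (1.11) and PMVK (1.07), and a median of 0.13 that changed sign with scaling (-0.10 to 0.35). Antigen presentation genes stood apart upward, with a median of 0.42 and 17 of 18 members above 0, of which HLA-DRB1 (1.07) passed the rule; HLA genes share reads with close relatives and are uncertain. Ribosome biogenesis genes had 5 members higher, among them FBL (1.10), the methyltransferase of nucleolar RNA, BOP1 (1.08) and PES1 (1.03), while the list median of 0.38 was not apart (percentile 77.25). Interferon-stimulated genes were split. BST2 (1.35) and IFI6 (1.17) were among 3 that were higher, and SAMD9L (-1.20) and SAMD9 (-1.18) among 3 that were lower, and the list median of -0.48 was no longer apart once random lists were matched on gene length too (percentile 14.57). HMMR (-1.20), a mitotic spindle gene, was lower and BIRC5 (1.01), which encodes survivin, higher, and the 30 G2 and M phase genes had a median of -0.13 (percentile 3.98), whose sign changed with scaling (-0.36 to 0.09) and which was apart with length-matched lists (percentile 0.10). S phase genes had a median of 0.18, of either sign by scaling, with FEN1 (1.18) higher. Immediate early genes had a median of -0.10, also of either sign, with KLF6 (-1.04) lower, and NF-kB genes a median of -0.24 with none past the rule.

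Transcripts with sites known to be edited by ADAR2 had a median of -0.40 in ADAR2 over 28 measured members (percentile 0.38), and 1 member, UNC80 (-1.05), passed the rule. CDK13 (-0.87), AZIN1 (-0.84) and GIPC1 (0.75) did not. The call of this list did not hold when random lists were also matched on gene length (percentile 2.90). Of 24 measured genes known to respond to the RUNX1-RUNX1T1 fusion, POU4F1 (-1.24) and CBFB (-1.09), the partner subunit of RUNX1, were lower, and the list median of 0.15, of either sign by scaling, was not apart. Granulocyte and monocyte genes had the same median of 0.15, also of either sign, with S100A9 (1.47) higher. The stress response list had a median of -0.19 (percentile 2.20) that became 0.02 with upper quartile scaling, with SLC7A11 (-1.36) among 3 lower members. KIT, a receptor of progenitors, was lower (-1.34, 542 against 1357 reads), and EGFL7 was higher (1.23), while the 9 measured stem and progenitor genes had medians of -0.35 in ADAR2, -0.13 in AR2-dsRBD and -0.07 in AR2-Cat, none apart except the first with length-matched lists (percentile 2.30).

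These differences moved together with signs of RNA composition in the ADAR2 library. The log2 ratio fell with gene length, with a Spearman correlation across genes of -0.36 against EV (-0.08 for AR2-dsRBD and -0.15 for AR2-Cat), where genes are not independent replicates. With genes in 10 equal groups by length, the shortest group had a median of 0.22 and the longest a median of -0.49. Several RNAs that lack a poly(A) tail were higher too, although such RNAs were scarce in all 4 libraries. RPPH1, the RNA of ribonuclease P, had a log2 ratio of 2.27, RN7SL1 of 1.73 and RMRP of 1.72, and 5 of 8 measured replication-dependent histone genes passed the rule upward, with H2BC9 (1.79) and H1-5 (1.42) among them, while H2BC5 (-1.27) was lower. The list of nuclear and small structured RNAs had a median of 0.65, with 5 of 10 members higher, 1 lower and 4 below 0. With the length trend removed, an alternative chosen after seeing the data, 573 genes were higher and 977 lower. The split into higher and lower also depended on scaling, as 27.9% of the calls were higher with TMM factors, 63.5% with upper quartile scaling and 6.7% with total counts alone. The median of all genes was -0.05, 0.16 and -0.29 under these scalings.

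**Figure D1:**
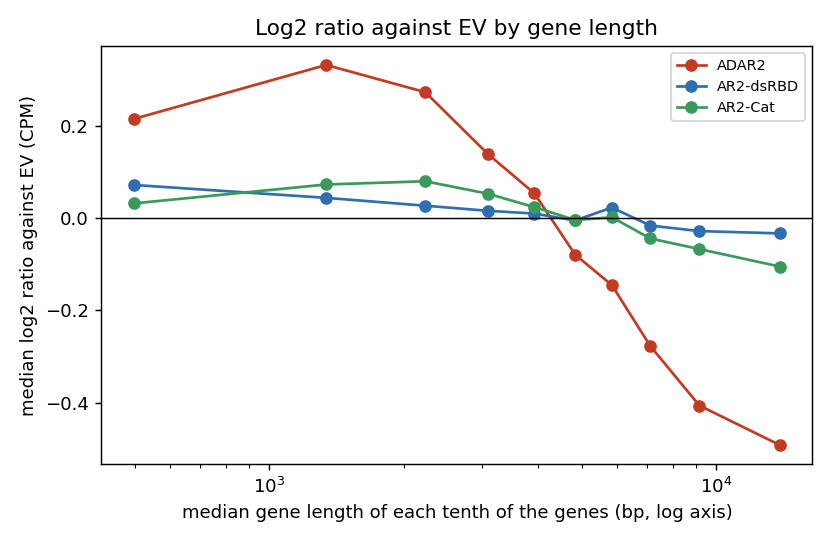
Median log2 ratio against EV (vertical axis) for 10 equal groups of genes by length of the gene model (horizontal axis, log scale, bp), in 3 lines for ADAR2, AR2-dsRBD and AR2-Cat, 1 library each. The ADAR2 line falls from 0.33 in the group with a median length of 1342 bp to -0.49 in the longest group, while the lines of both mutants stay between -0.11 and 0.08.

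In the AR2-dsRBD library, genes of the integrated stress response were far lower than in EV, and heat shock genes, many of which encode cytosolic chaperones, were higher as a list. DDIT4, an inhibitor of the growth kinase mTORC1, had 511 against 8422 reads (log2 ratio -3.71, 95% counting interval -3.90 to -3.53). CHAC1 (-3.10), TRIB3 (-2.96), SLC7A11 (-2.77), the cystine transporter, SESN2 (-2.54) and the transcription factor gene ATF3 (-2.51) followed. All of these are known targets of the transcription factor ATF4. The stress response list of 30 genes had a median of -0.67, below all matched random lists (percentile 0.00), with 11 members lower and 3 higher. The list holds members of opposite movement. All 15 of its amino acid response members lay below 0, with a median of -1.79 and 11 past the rule, including ASNS (-1.86), asparagine synthetase, PHGDH (-1.79) and CEBPB (-1.61). Of the 15 endoplasmic reticulum members 11 lay above 0, with a median of 0.61, and the 3 past the rule were SDF2L1 (1.30), MANF (1.20) and CALR (1.19), which encodes calreticulin. The split of the list by known function, and ASNS, PHGDH and the 3 last genes, were chosen after the values were seen.

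A total of 140 genes were higher and 335 lower in AR2-dsRBD than in EV. The widest lower ratios included the genes of the secreted factors STC2 and INHBE. GDAP1L1 had 0 against 443 reads, at least 118-fold lower on the floor of 3 single reads in the library, and PAPPA2 had 0 against 200 reads, at least 53.2-fold lower. Where mates are taken as pairs, by halved counts, the 95% intervals of these 2 ratios begin lower, at 47.7 and 21.3. STC2, stanniocalcin 2, had 10 against 975 reads (66.4-fold lower), INHBE 15 against 366 (17.6-fold), CNTN4 7 against 275 (25.3-fold), SCN4A 26 against 516 (14.9-fold), DDIT4 was 13.1-fold lower, and NLRP12, a regulator of inflammation in myeloid cells, had 67 against 1123 reads (13.1-fold). DCSTAMP had 2 against 240 reads, a ratio of 95.8 with a counting interval of 16.9 to 3820, and KLHDC7B 2 against 184, a ratio of 73.5 with an interval of 12.9 to 2930. These 2 are plain ratios of CPM, and with the prior count that the other folds carry they were 51.6 and 39.6. The widest higher ratios after ADARB1 were those of S100A8 (5.99-fold), CORO2A (4.23-fold), IL7R (3.89-fold, 1495 against 480 reads), the interleukin 7 receptor, SERPINB2 (3.57-fold), MYLK2 (3.22-fold), HMOX1 (3.17-fold), OSR2 (2.79-fold), IGLL1 (2.73-fold, 4771 against 2186 reads) and SPR (2.71-fold), which encodes sepiapterin reductase.

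Heat shock, ribosome biogenesis, cell cycle, cholesterol synthesis and respiration lists lay higher in AR2-dsRBD, and the cytosolic ribosomal protein list lower (median -0.09, percentile 0.18, 44 of 53 members below 0). Heat shock genes had a median of 0.87 with 6 of 15 members past the rule, among them HSPH1 (1.38), HSPA8 (1.34) and DNAJA1 (1.19). HSPE1 (1.35), the mitochondrial cochaperonin, shares reads with the read-through gene HSPE1-MOB4 and is uncertain. MYC target and ribosome biogenesis genes had a median of 0.45 with 27 of 28 members above 0, including NOP2 (0.76) and CAD (0.75). S phase genes had a median of 0.29 and 27 of 31 above 0, where FEN1 (1.00), a flap endonuclease, was higher and CDT1 (-1.09), a replication licensing factor, lower. G2 and M phase genes had a median of 0.27, 27 of 30 above 0 and none past the rule, with CKS2 at 0.77 and CDC20 at 0.70. Cholesterol synthesis genes had a median of 0.43, and STARD4 (1.04) and SQLE (1.01), a squalene-oxidising enzyme gene, were past the rule. All 32 nuclear oxidative phosphorylation genes lay above 0, with a median of 0.42 and none past the rule.

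Inflammatory groups lay lower in AR2-dsRBD. BCL3 (-1.67), CCL5 (-1.52), a chemokine, and ICAM1 (-1.33), an adhesion molecule, were lower among 12 NF-kB genes with a median of -0.30. Interferon-stimulated genes had a median of -0.22, with XAF1 (-1.45) and MX1 (-1.18) past the rule, and this list was no longer apart when random lists were matched on gene length (percentile 3.40). VEGFA, the vascular growth factor, was lower (-1.73, 6229 against 25878 reads), although the glycolysis and hypoxia list as a whole had a median of 0.02, of either sign by scaling. Genes known to respond to the RUNX1-RUNX1T1 fusion had a median of -0.15, with JUP (-1.06) lower and ID1 (1.06) higher, and granulocyte and monocyte genes a median of -0.19, with CEBPB lower and S100A8 and S100A9 (1.31) higher. Some RNAs without a poly(A) tail moved in the opposite way to ADAR2, although RN7SL1 (0.20) did not. RN7SK (-1.97), RPPH1 (-1.23) and RMRP (-1.14) were lower, and 4 of 8 histone genes were lower, with H2BC9 (1.06) higher. Mitochondrially encoded mRNAs had a median of -0.32, below 0 as in ADAR2. Immediate early genes had a median of -0.20, with ATF3 past the rule. The ADAR2-edited transcripts had a median of -0.07 with no member past the rule.

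**Figure D2:**
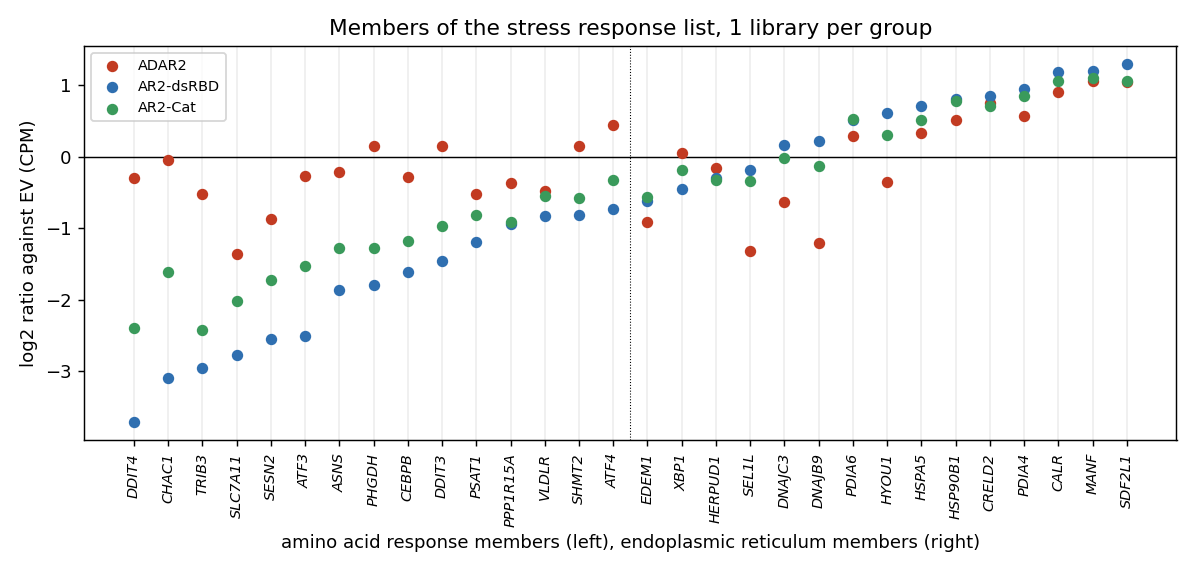
Log2 ratio against EV (vertical axis, CPM) for the 30 members of the stress response list (horizontal axis), 15 amino acid response members left of the dotted line and 15 endoplasmic reticulum members right of it, 1 point per library for ADAR2, AR2-dsRBD and AR2-Cat. All 15 amino acid response members lie below 0 in both mutants, down to DDIT4 at -3.71, and 11 of 15 do in ADAR2.

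The AR2-Cat library differed from EV in many, but not all, of the same gene groups, with smaller ratios in the stress response. TRIB3 (-2.42), DDIT4 (-2.39), SLC7A11 (-2.02), SESN2 (-1.72), CHAC1 (-1.61) and ATF3 (-1.53) were lower. All 15 amino acid response members again lay below 0, with a median of -1.27 and 9 past the rule, and the 15 endoplasmic reticulum members had a median of 0.52, with 9 above 0, 6 below 0 and 3 past the rule upward. Heat shock genes had a median of 0.72, and HSPE1 (1.40), HSPH1 (1.19), HSPA8 (1.16) and FKBP4 (1.13) were among 5 that were higher.

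Here 87 genes were higher and 316 lower than in EV. S100A8 (4.73-fold), MYLK2 (4.06-fold), S100A9 (3.03-fold), IL7R (2.91-fold), HMOX1 (2.75-fold), SPR (2.73-fold), TLCD1 (2.66-fold), HSPE1 (2.64-fold) and ASGR1 (2.61-fold) had the widest higher ratios after ADARB1. The lower end was led by GDAP1L1 with 2 against 443 reads, a ratio of 186 with a counting interval of 33.1 to 7380. NUPR1, a stress-induced chromatin regulator, had 2 against 260 reads, a ratio of 109 (19.2 to 4340), and PAPPA2 2 against 200, a ratio of 83.8 (14.7 to 3340). With the prior count these 3 plain ratios were 97.2, 57.3 and 44.2, on the scale of the other folds. KLHDC7B (26.7-fold), DCSTAMP (14.7-fold), STC2 (11.7-fold), MOCOS (10.5-fold), S100P (9.07-fold), NLRP12 (6.65-fold) and SCN4A (6.05-fold) followed.

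Cholesterol synthesis (median 0.55), MYC target and ribosome biogenesis (0.49), S phase (0.31) and G2 and M phase genes (0.29) lay higher in AR2-Cat as lists, with 21 of 23, 27 of 28, 29 of 31 and 27 of 30 members above 0. Few single members passed the rule, FEN1 (1.10) among them, and SQLE reached 0.95. The 32 nuclear oxidative phosphorylation genes had a median of 0.61, and UQCR10 and NDUFS5 both stood at 1.00 without passing the limit before rounding. ICAM1 (-2.06) and BCL3 (-1.53) were lower among NF-kB genes (median -0.26), XAF1 (-1.15) among interferon-stimulated genes (median -0.23, percentile 5.53 when random lists were matched on gene length), and VEGFA had a log2 ratio of -1.62 in a glycolysis and hypoxia list with a median of 0.12. The RUNX1-RUNX1T1 responsive list had a median of -0.21 with no member past the rule, UBASH3B at -0.74 being the widest. ADAR2-edited transcripts had a median of -0.17 (percentile 0.13), which became -0.05 and was not apart among genes of at least 5 CPM, also with no member past the rule, and CCNI at -0.54. RN7SK (-1.59) and RPPH1 (-1.37) were lower, as in AR2-dsRBD, RN7SL1 stood at 0.32, mitochondrially encoded mRNAs had a median of -0.42, and immediate early genes of -0.29. Granulocyte and monocyte genes had a median of -0.20 that was not apart (percentile 2.60, and 1.21 with length-matched lists, where it was), and histone genes of -0.34. Unlike in AR2-dsRBD, the histone list (percentile 17.68) and the cytosolic ribosomal protein list (percentile 46.01) were not apart. The ribosomal protein genes had a median of 0.15, with 50 of 53 members above 0.

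The calls of both mutants overlapped. Of the genes higher than in EV, 53 were shared by AR2-dsRBD and AR2-Cat, and of the genes lower, 204. Independent lists of these sizes would share 0.8 and 6.7 genes. In a simulation of 3 unchanged libraries with spread drawn from the ratios between both mutants, 18.6 higher and 16.8 lower calls were shared on average over 100 draws, from lists of 73.4 to 75.8 calls. Counting error was added to ratios that already hold it. The simulated lists were thus longer than the 55 higher and 36 lower calls between both mutants. The observed lists of lower genes were longer still, at 335 and 316 calls, so the simulated overlap is not one for lists of that size. Both mutants are also the closest pair, so an EV library that differed more by itself was not modelled. Part of the excess may come from the single EV library that both comparisons share. Of the 53 shared higher genes 26 were also higher in ADAR2 than in EV, and of the 204 shared lower genes 73 were also lower there.

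**Figure D3:**
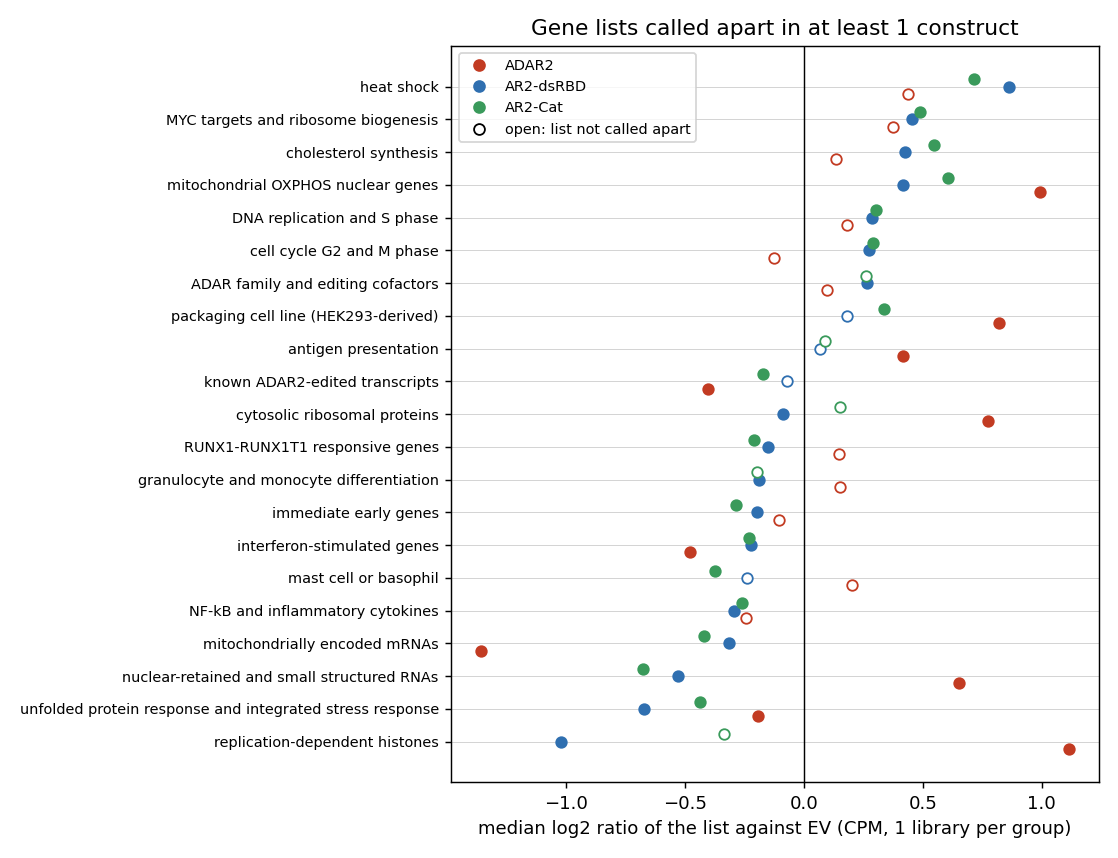
Median log2 ratio against EV (horizontal axis, CPM) of each fixed gene list (vertical axis) that stood apart from matched random lists in at least 1 construct, 1 point per library for ADAR2, AR2-dsRBD and AR2-Cat. Filled points mark lists called apart and open points lists that were not. Heat shock lies at 0.87, 0.72 and 0.44 in AR2-dsRBD, AR2-Cat and ADAR2, and mitochondrially encoded mRNAs at -1.36 in ADAR2.

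ADAR2 was then set against each mutant, the comparisons without EV. The stress response list was apart upward against AR2-dsRBD (median 0.43, percentile 99.79) and not apart against AR2-Cat (median 0.19, percentile 91.77, 12 of 30 members below 0). Against AR2-dsRBD, STC2 (29.7-fold, 440 against 10 reads), INHBE (12.6-fold) and DDIT4 (10.7-fold, 6932 against 511 reads) were higher, GDAP1L1 had 102 against 0 reads (at least 26.8-fold higher on the same floor, with a log2 interval from 3.40 by halved counts), and DCSTAMP had 228 against 2 reads. Against AR2-Cat, NUPR1 had 232 against 2 reads and GDAP1L1 102 against 2, and DCSTAMP (13.8-fold), PNCK (7.11-fold) and AIG1 (6.49-fold) were higher. CCDC144A was 14-fold lower in ADAR2 than in AR2-dsRBD and 9.99-fold lower than in AR2-Cat. RAB39A, a small GTPase (12.6-fold and 7.62-fold), NCR3LG1, a ligand of a natural killer cell receptor (7.99-fold and 4.91-fold), and MARCHF1, a ubiquitin ligase (6.88-fold and 6.77-fold), were lower against both. BDP1 was 6.35-fold lower than in AR2-dsRBD, and GCH1 5.33-fold lower than in AR2-Cat.

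Counts of calls were 611 higher and 1380 lower in ADAR2 than in AR2-dsRBD, and 381 higher and 944 lower than in AR2-Cat. Heat shock genes had medians of -0.32 and -0.34, with 3 and 2 members lower, and G2 and M phase genes medians of -0.41 and -0.43, with 4 members lower in each. Cytosolic ribosomal protein genes had medians of 0.84 and 0.60, nuclear oxidative phosphorylation genes of 0.59 and 0.33, and granulocyte and monocyte genes of 0.44 and 0.41. Mitochondrially encoded mRNAs had medians of -1.02 and -1.02, with 7 of 13 members lower in each, and the nuclear and small structured RNAs medians of 1.02 and 0.91, with 5 of 10 members higher and 4 below 0 in each. With upper quartile scaling the share of calls that were higher in ADAR2 went from 30.7% to 60.3% against AR2-dsRBD and from 28.8% to 59.7% against AR2-Cat, and with total counts it was 10.8% and 12.3%.

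Over the kept genes, both mutants lay closest to each other. Without the CPM filter the closest pair was AR2-dsRBD and EV, at a standard deviation of 0.638 against 0.644 for both mutants. There were 55 genes higher and 36 lower in AR2-dsRBD than in AR2-Cat, and the standard deviation over genes of the log2 ratio was 0.26, against 0.43 to 0.69 for the other 5 pairs. CCDC17 (3.19-fold), FAM221A (2.88-fold), CORO2A (2.76-fold), the receptor kinase gene ROS1 (2.66-fold) and OLIG1 (2.47-fold, 704 against 298 reads) were higher in AR2-dsRBD. GNAI1 (2.95-fold), CHAC1 (2.81-fold, 959 against 2831 reads), DDIT4 (2.5-fold), MUC12 (2.30-fold) and LTB (2.21-fold), lymphotoxin beta, were lower. The stress response list had a median of -0.15 in AR2-dsRBD against AR2-Cat (percentile 0.02), cytosolic ribosomal protein genes of -0.24 and nuclear oxidative phosphorylation genes of -0.20, with no ribosomal or respiratory member past the rule. The share of higher calls went from 60.4% to 72.8% with total counts, but to 44.4% at 5 CPM and 45.7% with protein-coding genes alone.

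Each library was also set against the other 3. A library close to another can hold few genes that stand apart, and over the kept genes both mutants were the closest pair. In ADAR2, 90 genes lay at least 1 above and 716 at least 1 below every other library. The total of 806 became 640 with upper quartile scaling and 1258 with total counts. Its split by direction is given for TMM factors alone. The ADAR2 library had the most counts but reads in the fewest genes, 25858 against 29188 in EV, 28625 in AR2-dsRBD and 26844 in AR2-Cat. FXYD1, PNCK, AIG1, PLAAT4 and SMIM1 stood above by 2.12, 2.09, 1.79, 1.79 and 1.72, and CCDC144A, MARCHF1, RAB39A, BDP1, a subunit of an RNA polymerase III initiation factor, and NCR3LG1 stood below by -3.32, -2.76, -2.54, -2.18 and -2.15. EV stood apart with 73 genes above and 26 below. PAPPA2 (4.64), KLHDC7B (2.96), KDM7A (2.49), a histone demethylase gene, GDAP1L1 (2.11) and P2RX7 (2.03), an ATP-gated channel with 3647 reads in EV and 794, 459 and 746 in the constructs, were above all constructs. ADARB1 (-4.74), S100A8 (-2.24), MYLK2 (-1.62), HMOX1 (-1.46) and SPR (-1.38) were below them. AR2-dsRBD had 8 genes above, with CORO2A (1.16) and SERPINB2 (1.03), and 20 below, with STC2 (-2.50), MIOX (-2.32), INHBE (-2.09), DCSTAMP (-1.81) and CDC42EP1 (-1.68). AR2-Cat had 1 above and 11 below, with NUPR1 (-3.02), CCDC17 (-1.68), FAM221A (-1.41) and ACSM1 (-1.19).

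Markers of other cells were few. Among genes of the packaging line used to make the virus, 7 of 18 were measurable, with a median of 0.82 in ADAR2, 0.18 in AR2-dsRBD and 0.34 in AR2-Cat, the first and last of them apart (percentiles 99.49 and 97.53). Neither call held at 5 CPM, and the AR2-Cat call was also lost with total counts (0.21), a prior count of 0.5 and the list mean (0.14). VGF (1.13, 241 against 108 reads) was the member past the rule. Fewer than 5 markers of T cells, natural killer cells, erythroid cells, macrophages and stroma were measurable, with medians of 0.29, 0.06, 0.09, 0.41 and 0.47 in ADAR2, 0.05, -0.33, -0.15, -0.11 and 0.06 in AR2-dsRBD, and -0.03, -0.28, -0.14, 0.00 and 0.05 in AR2-Cat. IL7R, in the T cell list, was higher in both mutants (1.96 and 1.54). B cell markers had medians of 0.50, -0.11 and 0.17, megakaryocyte markers of -0.06, -0.35 and -0.45, and mast cell or basophil markers of 0.20, -0.24 and -0.37, in ADAR2, AR2-dsRBD and AR2-Cat. The last of these medians was apart from matched random lists (percentile 1.76) but not without the CPM filter, at 5 CPM (-0.09) or by the list mean, with TPSB2 (-1.22), a tryptase with close paralogs and so uncertain, lower. Azurophil granule genes had medians of 0.44, 0.12 and 0.11 with no member past the rule, COPI coat genes of 0.10, 0.01 and 0.04, the oligomeric Golgi complex genes of 0.04, -0.08 and 0.02, p53 target genes of -0.12, 0.09 and 0.04, and apoptosis genes of -0.38, 0.04 and -0.06, none of them apart. In ADAR2 the medians of megakaryocyte, mast cell, COPI, oligomeric Golgi complex and p53 target genes changed sign with scaling, and in the mutants those of COPI, p53 and Golgi complex genes did so in at least 1 of them. Other list calls against EV that at least 1 setting ended were those of the ADAR2-edited, interferon-stimulated, stress response, histone and small RNA lists in ADAR2, of the RUNX1-RUNX1T1 responsive, granulocyte and monocyte, interferon-stimulated, immediate early, ribosomal protein and histone lists in AR2-dsRBD, and of the interferon-stimulated and NF-kB lists in AR2-Cat.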

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

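No paired analysis was possible because each group holds 1 library, and no setting replaces a replicate. The alternatives were planned except for removal of the length trend, intervals from read pairs, TMM factors without the ADAR2 library and lists matched on length, which were chosen after seeing the data. Values are genes higher and lower, and the cause of a shift was not tested unless the construction shows it.

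Total counts gave 187 and 2588 for ADAR2 against EV, 274 and 2259 against AR2-dsRBD, and 212 and 1516 against AR2-Cat, 83 higher in AR2-dsRBD than in AR2-Cat, and 1258 genes standing apart in ADAR2. Upper quartile scaling gave 1438 and 826, 1289 and 849, and 784 and 529 for the same ADAR2 pairs. With it the stress response list in ADAR2 turned to 0.025. The deposited RPKM values gave 222 and 2435 for ADAR2 against EV, 305 and 2126 against AR2-dsRBD, and 237 higher than in AR2-Cat.

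Without the CPM filter, which lets more genes in, counts were 1052 and 2267 (ADAR2 against EV), 434 and 754 (AR2-dsRBD against EV), 338 and 868 (AR2-Cat against EV), 1157 higher in ADAR2 than in AR2-dsRBD, 998 and 1491 (ADAR2 against AR2-Cat), and 412 and 249 (AR2-dsRBD against AR2-Cat). Genes standing apart were 350 in EV, 1741 in ADAR2, 275 in AR2-dsRBD and 361 in AR2-Cat, and the closest pair became AR2-dsRBD and EV. At 5 CPM, which tests fewer genes, counts for the 6 pairs in this order were 349 and 953, 50 and 138, 35 and 115, then 302 and 906 (ADAR2 against AR2-dsRBD), 114 and 599, and 4 and 5. Genes standing apart were 45, 498, 4 and 0. Protein-coding genes alone, again fewer, gave 381 and 984, 78 and 216, 47 and 200, 399 and 895, 226 and 601, and 16 and 19, with 501 genes apart in ADAR2, 11 in AR2-dsRBD and 7 in AR2-Cat.

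With the length trend removed, 977 genes were lower in ADAR2 than in EV. Without mitochondrial, ribosomal RNA and small RNA genes the small RNA list in ADAR2 had a median of -0.776, because most of its members are taken out. Of the 2072, 475 and 403 calls against EV, 1404, 448 and 364 were kept with upper quartile scaling, 1228, 439 and 371 with the length trend removed, and 1302, 188 and 150 at 5 CPM. Of the lists called, 4 of 10, 11 of 17 and 11 of 16 held under all 14 settings.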

Other observations

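The tests weighed here were chosen after the result was seen, except the count of libraries per construct, which was chosen before the data were examined. Thinning to equal depth was a planned setting, but its use as a test here was set after the result was seen.

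Gene families were chosen after the values were seen. The 20 cytosolic aminoacyl-tRNA synthetase genes had medians of -0.47 in AR2-dsRBD and -0.32 in AR2-Cat against EV, below all matched random lists, and of 0.10 in ADAR2, where the sign changed with scaling. WARS1 had log2 ratios of -1.46 in AR2-dsRBD and -1.17 in AR2-Cat, and CARS1 of -1.20 in AR2-dsRBD. FARSA (0.57 and 0.53) and RARS1 (0.51 and 0.75) lay above 0, as did 6 and 7 of the 20 in all, and 2 and 1 members passed the rule downward. The 12 amino acid transporters of the SLC7 and SLC38 families, with SLC7A11 of the stress response list among them, had medians of -0.64 in ADAR2, -0.22 in AR2-dsRBD and -0.24 in AR2-Cat. SLC7A11 (-1.36, -2.77 and -2.02) and SLC7A5 (-0.15, -0.85 and -0.70) were lower in the mutants than in ADAR2. SLC38A1 was lower in all 3 (-1.47, -1.82 and -1.42) and SLC38A5 higher (1.13, 1.13 and 1.10).

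Some gene families lay higher in all 3 constructs. The 38 proteasome subunits had medians of 0.58, 0.19 and 0.37 in ADAR2, AR2-dsRBD and AR2-Cat, and the 77 mitochondrial ribosomal proteins of 0.64, 0.20 and 0.37. The 8 CCT chaperonin subunits were apart in the mutants (0.39 and 0.42) and not in ADAR2 (0.33, percentile 38.71). The 37 DNAJ cochaperones were not apart (0.04, 0.10 and 0.12), except in AR2-Cat with length-matched lists (98.44), and the sign in ADAR2 changed with scaling. The 388 zinc finger genes named ZNF had a median of -0.33 in ADAR2, -0.08 in AR2-dsRBD and -0.12 in AR2-Cat. When random lists were matched on length the first 2 were not apart (percentiles 4.12 and 5.98) and the last was (0.83).

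More genes stood apart in the ADAR2 library than in any other library. The totals of 28 in AR2-dsRBD and 12 in AR2-Cat are held down by the closeness of both mutants to each other. They are thus not on equal terms with the 806 in ADAR2. A smooth trend with the length of the gene model is unlikely as the sole source. With that trend removed 544 genes still stood apart, against at most 80 in another library. The removal left the spread among genes of like length, so a length bias that varies between transcripts was not tested. Sequencing depth as the source is also unlikely, since 784 stood apart after thinning to the shallowest library. An effect of the construct and of a single culture or library preparation cannot be told apart with 1 ADAR2 library, and the low mitochondrial share of that library (1.00% of counts) keeps the question open. Further libraries of each construct would settle it.

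Amino acid response genes were lower in both mutant libraries than in EV. Library scaling is an unlikely source, since a library factor moves all genes alike. The median of these genes differed from that of all genes by -1.27 in AR2-Cat and -1.80 in AR2-dsRBD. These members too were set apart after the values were seen, so the size of that gap is no support. The whole stress response list, fixed beforehand, had medians of -0.69 to -0.66 in AR2-dsRBD and -0.52 to -0.41 in AR2-Cat by scaling. Lower endoplasmic reticulum stress as a whole stays open, as the endoplasmic reticulum members had a lower median of the 2 mutants of 0.52 but were set apart after the values were seen, and 6 of 15 lay below 0 in AR2-Cat. The state of the single EV culture, such as its supply of amino acids, stays open, and the median in ADAR2 against EV was -0.28, or -0.51 to -0.06 by scaling. In ADAR2 against AR2-dsRBD, where EV has no part, the whole stress response list was apart upward (median 0.43, 11 members higher and 2 lower). Against AR2-Cat the list was not apart (median 0.19, 7 higher and 1 lower), and ADAR2 too is 1 library. With 1 EV library, a part of the EV culture in the ratios against EV cannot be told apart from an effect of the mutants.

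RUNX1T1 had no reads in any of the libraries labelled Kasumi-1. A counting loss of the chromosome region is unlikely, because 3 of the 4 nearest protein-coding genes had 50 or more reads, among them OTUD6B with 3811 in EV. Cells without the RUNX1-RUNX1T1 fusion are a candidate explanation, and the highest CD34 level of 0.161 CPM goes with it. CD34 is 1 marker, and other genes do not decide. Among genes known to respond to the fusion, POU4F1 was measurable at 0.907 to 2.16 CPM. Of the 32 such genes in the tables, 8 were under 1 CPM in every library. Loss of RUNX1T1 alone from the counting remains possible. A rule that drops reads of overlapping features is argued against, for the features looked at, by RN7SK and 7SK with 1746 reads each in EV. EEF1G and ENSG00000255508, at 391763 and 396321 reads in EV, argue the same way. Loss of RUNX1T1 alone from the counting would not account for the low CD34 level. Fusion reads or a genetic profile of the cells would decide, and neither was analysed here.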
